A study of Mus musculus with 13 samples.

How the data were processed

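Single-cell RNA libraries were made from mouse tumours of the Pan02 cell line, a pancreatic adenocarcinoma line, and fall into 4 groups by the labels: control and coixenolide on each of 2 diets, CD and HFD. There were 3 libraries in each group and 4 in the HFD coixenolide group. Coixenolide is a lipid compound of Coix seed. Per the labels' protocols, tumour tissue was taken apart in a nuclear extraction buffer and the suspension was loaded on a GEXSCOPE microfluidic device, in which each cell's mRNA is caught and given a cell barcode and a UMI, a tag that lets copies of one molecule be counted once. Ribosomal protein genes held 5.57 to 17.2% of the UMIs of a library, and the barcodes are called cells throughout. Nothing in the sources used here says whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

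The deposited files hold raw UMI counts per gene and cell barcode, 1 sparse matrix per library, already limited to barcodes that passed a depth minimum (the lowest barcode of a library held 2267 to 4440 UMIs). The aligner, the counting tool and the filter on barcodes are not given in the sources used here. Per the submitters' processing notes, the listed build is GRCh38, a human build, while the gene IDs in the files are mouse Ensembl IDs. For this reason no coordinates are given. Gene names are the symbols that the files pair with those IDs, and the 118 symbols shared by several IDs were kept apart by ID. The gene lists of the libraries differed in length, with 53715 genes listed for any library and 17259 for every library, and a gene missing from a list was counted as 0. A barcode list was used for 9 libraries, and the other 4 were read by column number alone.

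Cells were kept with at least 200 genes detected and under 20% mitochondrial UMIs, which removed 190 of 90160 barcodes. Scrublet in scanpy 1.11.5 was run on each library and its 629 doublet calls (0.699%) were removed. In 5 large libraries it called under 0.5% of the cells, so it had not worked there, and doublets remain in the data. These were all controls, namely CD control 1 and 3 and HFD control 1 to 3. By comparison, 0.921, 0.436, 1.59 and 1.53% were called in HFD coixenolide 1 to 4. In CD control 2 it called 2.29%, and in CD coixenolide 1 to 3 0.0667, 0 and 1.29%. Doublets left in may thus differ between control and coixenolide libraries. Counts of the 89341 cells kept were scaled to 10000 per cell and log transformed. The 2000 most variable genes, 30 principal components and 15 nearest neighbours were used for Leiden clustering at resolution 1 (leidenalg 0.10.2), with no integration of libraries. Clusters were named from marker lists fixed before the data were examined, with at least 3 markers at 2-fold or more over the other clusters. The names mean "X-like" and rest on these markers alone. The malignant list holds epithelial genes, which normal duct cells also express, so after the data were seen the UMIs of Y-linked genes, near 0 in the clusters of tumour cells, were used to tell duct clusters from malignant clusters. A group of 7 clusters stayed unnamed, because they joined markers of several classes or their leading genes went against the best name.

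UMI counts were summed per library over all cells, and over the macrophage, duct and dendritic classes, the 3 largest with at least 20 cells in at least 2 libraries of every group. The malignant class did not meet that rule in the CD coixenolide group. It was tested in the HFD groups and in the controls by a choice made after the data were seen. The sums were tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood test with TMM scaling and the edgeR filter on low counts, in a single model per class over all groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled. DESeq2 1.42.0 was the other tool. In each of 18 combinations of class and contrast, 24 gene lists fixed before the data were examined were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation. Of the 432 tests, 166 passed with the preset value and 1 with an estimated correlation. The lists described are those with the lowest p-values, up to 2 for each class and contrast.

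The rule for named genes was also fixed beforehand. It takes genes past the threshold with at least 10 CPM in the higher group and no overlap between the groups, and, where fewer than 3 qualify, the 5 lowest p-values at that CPM as values that did not pass. Predicted, mitochondrial and ribosomal protein genes were left out of it. No gene passed, so the second part applied throughout. Up to 4 members per list are named by lowest p-value. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here.

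Shares of cells in each class were compared as log2 odds, with 0.5 added to both counts, by two-sided exact permutation tests with SciPy 1.17.1. Labels were permuted within a diet or treatment and the differences averaged, and p-values were adjusted over 14 classes. In a test of 3 libraries against 3 the smallest possible p is 0.1, in 4 against 3 it is 0.0286, and in the stratified test 0.00143. Intervals of shares are exact binomial at 95% and, like the limits allowed by a count of 0, cover counting error only.

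The gene test was tested on simulated data, with counts drawn from the means of the real libraries and 200 changed genes in each of 3 simulations. For coixenolide in CD, the macrophage sums (12164 genes) gave back 60.0% of 4-fold and 80.0% of 8-fold changes. The all-cell sums (19718 genes) gave back 14.7% and 40.7%. Each gene had the same mean in all libraries before the changes, and genes were drawn independently. Library types and the mix of clusters were left out, so recovery in the real libraries may be lower. Alternatives were another scaling, DESeq2, no filter on low counts, a fit of the compared groups alone, a block on the replicate number, genes listed for every library, 500 genes per cell, doublets kept, resolution 2, and each library left out in turn. Added after the data were seen were the removal of the top 5% of doublet scores, the removal of the 3 libraries with no malignant cells, and library type as a term in the model.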

Results

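Tumours grown from Pan02 cells, a mouse pancreatic adenocarcinoma line, were profiled cell by cell in mice on 2 diets, CD and HFD, with or without coixenolide. The series asks how coixenolide alters gene expression of the tumours on each diet. The groups were CD control, CD coixenolide and HFD control, with 3 libraries each, and HFD coixenolide, with 4. The CD control libraries held 67942623, 69255339 and 116719622 UMIs, and the CD coixenolide libraries 17484904, 18848891 and 76460308. The HFD control libraries held 74837162, 91303694 and 65432200 UMIs, and the HFD coixenolide libraries 67306903, 53851355, 69760081 and 63215966. Between 2996 and 10674 cells were kept per library, 89341 in all.

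The cells fell into 37 clusters, of which 30 were named as 14 classes. The malignant-like class was the largest, with 34276 cells, and its clusters were led by genes such as Prkg2, Fst and Bmp4. Y-linked genes stood at 3.21 CPM in it and at 38.3 to 136 CPM in the other 13 classes. Macrophages numbered 16760, in 4 clusters. The complement genes C1qa, C1qb and C1qc with Mrc1 were among the leading genes of clusters 6 and 12, Mmp12, Gpnmb, Lpl, Cd36 and Trem2 of cluster 8, and Mgl2, Ccl6 and Ly6i of cluster 9. Of the remaining classes, duct-like epithelium held 9960 cells, dendritic cells 6098, plasma cells 4529, T cells 4164, endothelial cells 2578 and fibroblasts 2229. The 2 duct clusters were led by Spink4, Mmp7 and Tff2 or by Ambp, Pigr and Tm4sf4. They held 15 markers of the malignant list, which is epithelial, and 5 and 6 duct markers, and were named duct after their Y-linked UMIs (91.4 and 108 CPM) were seen. B cells, neutrophils, erythroid, endocrine, acinar and mural cells numbered 255 to 1031 each. The unnamed clusters held 5275 cells (5.90%), with a mean share of 9.27 ± 10.8% in CD control, 3.21 ± 5.48% in CD coixenolide, 3.95 ± 1.32% in HFD control and 3.85 ± 3.22% in HFD coixenolide libraries (SD, n = 3, 3, 3 and 4). In CD control 1 they made up 21.5% of the cells, almost all from a cluster led by Saa3, Marco and Arg1, genes of activated myeloid cells.

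**Figure D1:**
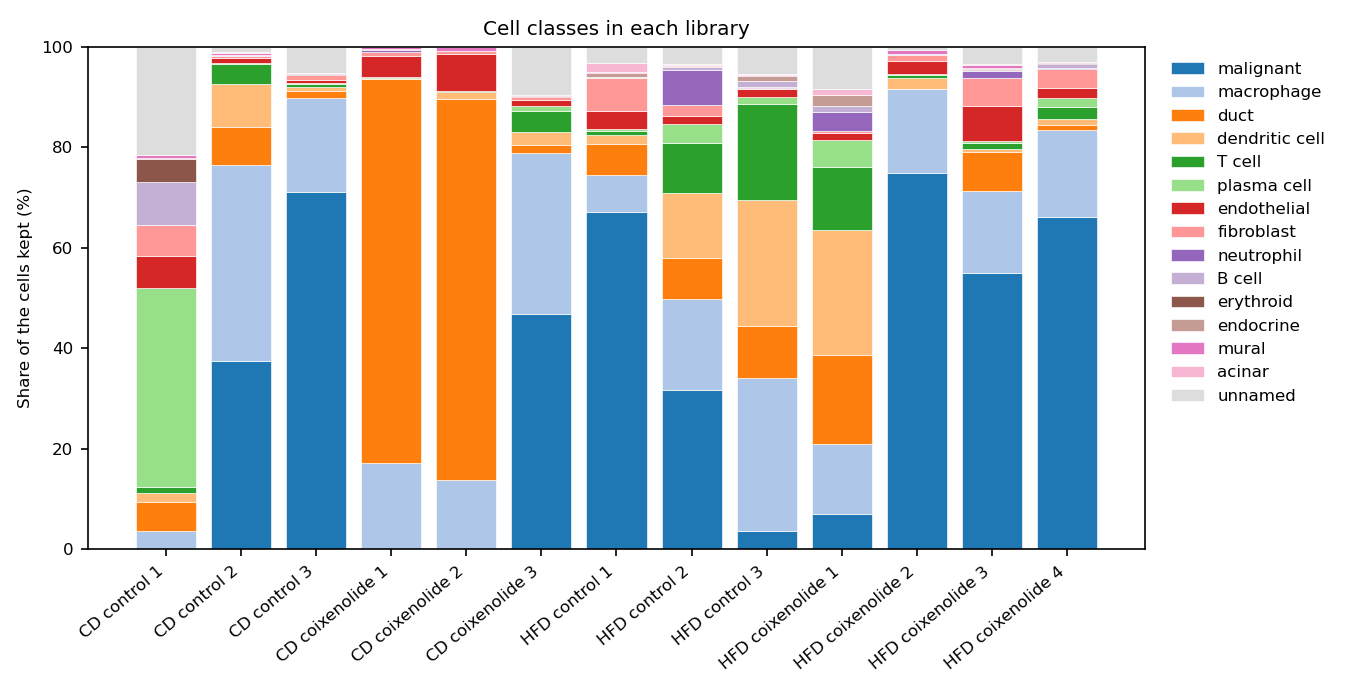
Share of the kept cells of each library in each class, in percent, with a bar per library and colours for the classes. Malignant-like cells range from 0% in CD control 1 and in CD coixenolide 1 and 2 to 74.9% in HFD coixenolide 2.

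The tumours of a group differed widely in their make-up. Malignant-like cells made up 36.2 ± 35.6% of CD control and 15.6 ± 27.1% of CD coixenolide libraries (SD, n = 3 each), and 34.1 ± 31.9% of HFD control (n = 3) and 50.8 ± 30.3% of HFD coixenolide libraries (n = 4). None were found in 3 libraries: 0 of 8674 cells in CD control 1, which allows a share of up to 0.0346%, 0 of 2996 in CD coixenolide 1 (up to 0.1001%) and 0 of 3261 in CD coixenolide 2 (up to 0.0920%). Duct cells instead formed 76.4% of CD coixenolide 1 (exact binomial 95% interval 74.8 to 77.9%) and 75.8% of CD coixenolide 2 (74.3 to 77.3%), and their mean share was 51.2 ± 43.1% in CD coixenolide against 4.89 ± 3.12% in CD control libraries (n = 3 each). Plasma cells, which secrete antibody, formed 39.6% of CD control 1 and at most 5.32% of the other libraries. Macrophages held 20.5 ± 17.8%, 21.01 ± 9.73%, 18.7 ± 11.7% and 16.1 ± 1.48% in CD control, CD coixenolide, HFD control and HFD coixenolide (n = 3, 3, 3 and 4).

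Neither diet nor coixenolide moved the share of a class beyond this spread. For coixenolide against control over both diets, the difference in log2 odds was -1.28 for malignant cells (p = 0.819, exact stratified permutation test, two-sided), 0.23 for macrophages (p = 0.771), 0.42 for duct cells (p = 0.903), -1.42 for dendritic cells (p = 0.217) and -1.52 for T cells (p = 0.204). For HFD against CD it was 5.57 for malignant cells (p = 0.106, same exact test), -0.12 for macrophages (p = 0.810), -2.19 for duct cells (p = 0.299), 1.72 for dendritic cells (p = 0.161) and 2.09 for T cells (p = 0.0971). The lowest adjusted p over 14 classes and 6 contrasts of these exact permutation tests was 0.336. Without the 3 libraries that lacked malignant cells, the malignant and duct differences turned sign in both contrasts.

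Under coixenolide in CD, the sums over all cells held less RNA of proliferation genes and more of fatty acid oxidation genes. All 31 proliferation genes were lower, with a median log2 difference of -1.47 (camera adjusted p = 8.58e-23, and adjusted p = 0.267 with an estimated correlation). Ezh2, the methyltransferase of Polycomb complex PRC2, stood at 17.6 ± 9.32 CPM against 43.2 ± 13.8 (log2 difference -1.29 ± 0.40 SE, n = 3 each), and Atad2, a chromatin ATPase, at 16.8 ± 14.95 against 54.1 ± 29.5. All 24 fatty acid oxidation genes tested were higher, with a median of 0.55 (camera adjusted p = 4.09e-09, and adjusted p = 0.266 with an estimated correlation). Ppara, the nuclear receptor that turns on this pathway, was at 0.760 ± 0.486 against 0.0999 ± 0.0167 CPM (log2 difference 2.87 ± 0.69) and passed when adjusted over the list alone, as the only member. Etfb, an electron carrier of beta oxidation, stood at 136 ± 49.3 against 71.6 ± 17.2 CPM. These sums moved with tissue make-up, since CD coixenolide 1 and 2 held 0 malignant cells and mainly duct cells.

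Among single genes in the all-cell sums, the lowest p-values for coixenolide in CD belonged to Pigyl (log2 difference 1.19 ± 0.24 SE), Stbd1, a glycogen-binding protein (1.92 ± 0.41), Rbm3, a cold-induced RNA-binding protein (-1.58 ± 0.34), St3gal4, a sialyltransferase (1.73 ± 0.38), and the chemokine gene Ccl27a (1.47 ± 0.33). Their groups did not overlap, yet each had an adjusted p of 0.570 in edgeR (n = 3 each). Of all genes tested here, 7.43% had groups without overlap, where chance gives 10%. With edgeR 0 of 19718 genes passed and 1691 had an unadjusted p under 0.05, where chance gives 986. DESeq2 called 83, and 14 of 24 lists passed camera with the preset correlation. Without CD coixenolide 3, which leaves CD coixenolide 1 and 2 alone in the group, edgeR called 825 genes. The median log2 difference of all genes was -0.11 here, and 0.12 for the interaction of diet and coixenolide over all cells.

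Macrophages of the CD coixenolide libraries held less RNA of the interferon response and of proliferation. All 30 interferon genes were lower, with a median log2 difference of -1.08 (camera adjusted p = 2.68e-14, and adjusted p = 0.593 with an estimated correlation). The helicase gene Ddx60 stood at 3.59 ± 2.38 against 11.1 ± 3.36 CPM (-1.56 ± 0.46 SE, n = 3 each) and Usp18, which curbs interferon signalling, at 7.82 ± 7.25 against 26.4 ± 8.51 CPM. All 31 proliferation genes were lower, with a median of -1.001 (camera adjusted p = 6.19e-15, and adjusted p = 0.593 with an estimated correlation), among them the mitotic kinesin Kif11 at 4.29 ± 5.60 against 11.8 ± 0.822 CPM. Genes of other cells were lower in the same sums, with 20 of 24 extracellular matrix genes (camera adjusted p = 0.0021, and adjusted p = 0.593 with an estimated correlation) and 8 of 9 cytotoxic lymphocyte genes (camera adjusted p = 0.0253, and adjusted p = 0.604 with an estimated correlation). Genes restricted to malignant cells summed to 10.7, 1.75 and 247 CPM in macrophages of CD coixenolide 1 to 3 and to 6.47, 62.9 and 103 in those of CD control 1 to 3. In the interferon and proliferation lists 0 members passed, over all genes or adjusted over the list alone. Most macrophages of CD coixenolide 1 and 2 and CD control 1 lay in cluster 8, and most of CD coixenolide 3 and CD control 2 and 3 in cluster 12.

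Single macrophage genes with the lowest p-values were Tmem267 (log2 difference 3.50 ± 0.73), the sodium pump subunit Atp1b1 (1.95 ± 0.42), the cell-cycle inhibitor Cdkn1c (3.87 ± 0.88), N4bp1 (-1.26 ± 0.30) and the small heat shock gene Hspb7 (6.92 ± 1.70), all at an adjusted p of 0.736. Cdkn1c and Hspb7 overlapped between the groups. Of 12164 genes, 0 passed in edgeR, 704 had an unadjusted p under 0.05 (608 by chance), and DESeq2 called 4. The lists that passed with the preset correlation numbered 14, and 7 without the 3 libraries that held no malignant cells. Without CD coixenolide 3, edgeR called 583 genes.

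Duct cells of the CD coixenolide libraries held less RNA of inflammatory genes and of class I antigen presentation. Of 22 NF-kB and inflammation genes, 20 were lower, with a median log2 difference of -1.88 (camera adjusted p = 1.49e-13, and adjusted p = 0.326 with an estimated correlation), and 10 passed when adjusted over the list alone against 0 over all genes. They included the NF-kB inhibitors Tnfaip3 (20.9 ± 5.02 against 50.3 ± 15.7 CPM, log2 difference -1.30 ± 0.34 SE, n = 3 each) and Nfkbia (523 ± 70.0 against 887 ± 261), the neutrophil chemokine Cxcl1 (70.3 ± 28.1 against 289 ± 61.2), and Saa3, an acute-phase protein (3.09 ± 2.53 against 324 ± 555). All 13 class I genes were lower, with a median of -0.91 (camera adjusted p = 6.60e-09, and adjusted p = 0.365 with an estimated correlation), and Nlrc5, the activator of class I genes, passed when adjusted over the list alone (3.17 ± 0.555 against 10.6 ± 2.72 CPM). CD control 1 set the level of Saa3, whose difference was 0.41 without the 3 libraries that held no malignant cells. An unnamed cluster led by Saa3 held 1838 cells of CD control 1 and at most 15 of any other library. Saa3 is thus not shown to be RNA of duct cells. Haemoglobin genes took 0.974% of the UMIs of CD control 1, against at most 0.199% in the other libraries.

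The duct genes with the lowest p-values were the haemoglobin scavenger Hp (-3.98 ± 0.70), the collagen-modifying enzyme P3h2 (3.57 ± 0.69), Guca1a (-1.44 ± 0.28), the haem-degrading enzyme Hmox1 (-1.70 ± 0.33) and the metalloreductase Steap4 (-3.41 ± 0.70), each at an adjusted p of 0.557 in edgeR. Of 13345 genes 0 passed, 1144 had an unadjusted p under 0.05 (667 by chance) and DESeq2 called 25. With the preset correlation 15 lists passed, and 2 without the libraries that lacked malignant cells. Without CD coixenolide 3, edgeR called 240 genes. Duct cells came mostly from cluster 16 in CD coixenolide 1 and 2 (2264 and 2400 cells) and from cluster 14 in the other 4 CD libraries.

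In dendritic cells, tested in 2 CD coixenolide and 3 CD control libraries, 26 of 29 interferon genes were lower, with a median log2 difference of -0.51 (camera adjusted p = 7.91e-05, and adjusted p = 0.897 with an estimated correlation). Isg15, a ubiquitin-like interferon product, stood at 257 ± 222 (n = 2) against 467 ± 139 CPM (n = 3). Proliferation genes were lower in 23 of 31 members, with a median of -0.22 (camera adjusted p = 9.72e-05, and adjusted p = 0.897 with an estimated correlation), and 0 members of either list passed, also when adjusted over the list alone. The lowest p-values were those of the DNA repair gene Alkbh3 (-1.67 ± 0.41), Pik3ip1 (-2.52 ± 0.73), Rrm2b (-3.15 ± 0.92), Golga5 (-1.38 ± 0.41) and the mast cell tryptase Tpsb2, at 39.3 ± 55.5 CPM (n = 2) with 0 UMIs in the controls. In edgeR 0 of 7770 genes passed and 157 had an unadjusted p under 0.05, and DESeq2 called 1. Malignant cells were present in 1 CD coixenolide library and were not compared in CD.

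Under coixenolide in HFD, macrophages held less RNA of lipid uptake and antioxidant genes. Of 24 lipid uptake and storage genes 20 were lower, with a median log2 difference of -0.32 (camera adjusted p = 1.16e-05, and adjusted p = 0.660 with an estimated correlation). Lpl, the lipase that frees fatty acids from lipoproteins, stood at 139 ± 49.9 CPM (n = 4) against 1641 ± 1360 in HFD control (n = 3; log2 difference -3.56 ± 1.35 SE). The fatty acid transporter Cd36 stood at 91.6 ± 35.3 against 873 ± 694 CPM, and the fatty acid binding protein Fabp5 at 222 ± 16.2 against 788 ± 377. Of 20 antioxidant and ferroptosis genes 16 were lower, with a median of -0.66 (camera adjusted p = 1.04e-05, and adjusted p = 0.660 with an estimated correlation), including the peroxidase Prdx1 (1617 ± 271 against 7621 ± 4760 CPM) and the ferritin chain Fth1 (8237 ± 1000 against 19403 ± 9932). Haemoglobin genes were higher in 4 of 4 in the same sums, with a median of 5.27 (camera adjusted p = 5.02e-05, and adjusted p = 0.660 with an estimated correlation), and 3 passed when adjusted over that list alone. Hbb-bs ran from 6.58 CPM in HFD coixenolide 4 to 347 in HFD coixenolide 3, where erythroid cells made up 0.358% of the cells against 0.0316 to 0.0774% in the HFD controls. In the lipid and antioxidant lists 0 members passed, over all genes or adjusted over the list alone.

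**Figure D2:**
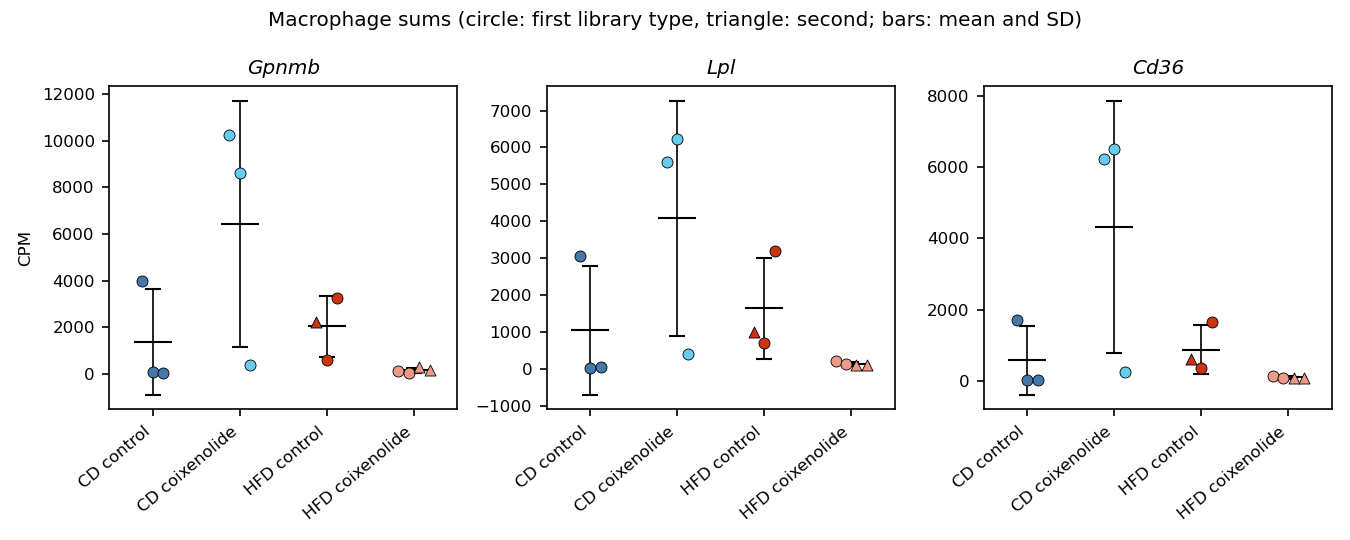
CPM of Gpnmb, Lpl and Cd36 in the macrophage sum of each library, by group, with bars for the mean and SD and marker shapes for the library type. All 4 HFD coixenolide libraries lie below all 3 HFD controls for each gene, and in CD the highest values belong to CD coixenolide 1 and 2 and CD control 1.

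The macrophage genes with the lowest p-values in this contrast were Mgst2, a glutathione transferase (-2.10 ± 0.52), Zfp637 (-0.48 ± 0.13), Ccdc163 (-0.66 ± 0.20), the mitochondrial sulphur transferase Tst (-2.19 ± 0.65) and Mettl21a (-0.69 ± 0.22), all with groups that did not overlap and an adjusted p of 1.00 in edgeR (n = 4 and 3). Of 12164 genes 0 passed, 221 had an unadjusted p under 0.05, where chance gives 608, and DESeq2 called 0. Groups did not overlap in 5.65% of these genes, where chance gives 5.71%. With the preset correlation 6 lists passed, and 3 without HFD control 3. Cluster 8 held most macrophages of HFD control 3, cluster 9 most of HFD coixenolide 1, and cluster 12 the largest part in the other HFD libraries. Cluster 8, led by Mmp12, Gpnmb, Lpl and Cd36, held 185 of 597, 234 of 1414 and 1235 of 1939 macrophages in HFD control 1 to 3. In HFD coixenolide 1 to 4 it held 44 of 1136, 26 of 689, 127 of 1240 and 109 of 1106. Lower lipid genes are thus not shown to be a change within a single kind of macrophage.

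Sums over all cells in HFD held less RNA of T cell regulation genes under coixenolide. The 13 T cell exhaustion and regulation genes tested were all lower, with a median of -0.82 (camera adjusted p = 0.00105, and adjusted p = 0.655 with an estimated correlation). Foxp3, the factor of regulatory T cells, stood at 3.57 ± 5.94 CPM (n = 4) against 14.9 ± 18.1 (n = 3), while T cells made up 4.22 ± 5.65% of HFD coixenolide and 9.95 ± 9.20% of HFD control libraries. Targets of MAPK and YAP signalling were higher in 16 of 17 members, with a median of 0.38 (camera adjusted p = 0.00138, and adjusted p = 0.655 with an estimated correlation), led by Ankrd1 (1.27 ± 1.15 SE), a gene among the leading ones of malignant clusters. Neither list had a member that passed, also when adjusted over the list alone. The lowest p-values were those of Lipa, the lysosomal acid lipase (66.2 ± 17.2 against 185 ± 76.7 CPM, log2 difference -1.48 ± 0.38), Vsig8 (-4.05 ± 1.17), Cyp2e1, a drug-metabolizing cytochrome (-9.27 ± 2.84), Ghrl, the ghrelin gene (-8.29 ± 2.57), and Gpnmb, a glycoprotein of phagocytes (-4.50 ± 1.42). Cyp2e1 rested on HFD control 2, at 231 CPM against at most 12.9 in any other library. In edgeR 0 genes passed and 110 had an unadjusted p under 0.05, where chance gives 986, and DESeq2 called 0. Lists past the preset test numbered 14, then 7 with library type as a term and 3 without HFD control 3.

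Duct cells of HFD coixenolide libraries held more RNA of cholesterol synthesis, with 22 of 22 genes higher and a median log2 difference of 0.63 (camera adjusted p = 6.00e-11, and adjusted p = 0.451 with an estimated correlation). Duct cells lay mostly in cluster 16 in HFD control 2 and 3 and HFD coixenolide 1 (517, 533 and 1154 cells), and in cluster 14 in HFD control 1 and HFD coixenolide 3 and 4 (489, 562 and 64). Nsdhl, an enzyme of its later steps, stood at 30.5 ± 12.003 against 17.8 ± 8.49 CPM (n = 3 each). Fatty acid oxidation genes were lower in 20 of 23, with a median of -0.34 (camera adjusted p = 7.91e-07, and adjusted p = 0.451 with an estimated correlation), among them Pdk4, a kinase that restrains pyruvate oxidation (-1.96 ± 1.10 SE). Macrophage genes led the list of lowest p-values in these duct sums, namely Mmp12 (-4.50 ± 1.29), Lpl (-4.06 ± 1.23) and Gpnmb (-4.27 ± 1.35), followed by Aldh1l1 (0.88 ± 0.28) and Slc5a8 (0.94 ± 0.34). With edgeR 0 genes passed, singly or adjusted over those lists alone, 53 had an unadjusted p under 0.05, and DESeq2 called 0.

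In dendritic cells of the HFD groups, 26 of 29 interferon genes were higher under coixenolide, with a median of 0.54 (camera adjusted p = 1.14e-05, and adjusted p = 0.683 with an estimated correlation). Isg15 stood at 277 ± 55.2 CPM (n = 4) against 158 ± 9.39 (n = 3), and Ifit1, an RNA sensor, at 129 ± 109 against 35.3 ± 10.8. Gpnmb had the lowest p-value (1.03 ± 1.59 against 40.7 ± 35.3 CPM, -5.69 ± 1.24 SE), followed by the decoy receptor Il1r2 (2.06 ± 0.55), Trem1 (2.34 ± 0.66), Gcnt1 (1.07 ± 0.31) and Gpr171 (1.20 ± 0.35). Il1r2 and Trem1 overlapped between the groups. Gpnmb is a leading gene of macrophage cluster 8 and is not shown to be RNA of dendritic cells. HFD coixenolide 2 to 4 held 90, 47 and 81 dendritic cells, against 2024 in HFD coixenolide 1, so low levels there rest on few UMIs. In edgeR 0 genes passed, 0 also when adjusted over the list alone, 63 had an unadjusted p under 0.05, and DESeq2 called 1. The interferon list was the 1 list to pass in this contrast, and leaving out single libraries gave 1 to 9 lists.

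Malignant cells of the HFD coixenolide tumours held more RNA of inflammatory genes, with 23 of 24 NF-kB genes higher and a median log2 difference of 0.74 (camera adjusted p = 4.23e-05, and adjusted p = 0.299 with an estimated correlation). The chemokine Ccl2 stood at 14.8 ± 9.20 CPM (n = 4) against 6.63 ± 1.39 (n = 3) and the cytokine Lif at 25.1 ± 17.9 against 8.60 ± 5.26. Malignant cells lay mostly in clusters 18 and 26 in HFD control 1 and 2 (3092 and 1685 cells), and in clusters 26, 36, 35 and 35 in HFD coixenolide 1 to 4 (336, 1902, 3079 and 3306). Cytotoxic lymphocyte genes were lower in 13 of 14, with a median of -0.58 (camera adjusted p = 0.000224, and adjusted p = 0.673 with an estimated correlation), at levels such as 1.82 ± 2.03 against 4.19 ± 3.38 CPM for Cd8a. These are T and NK cell genes, and T cells made up 4.22 ± 5.65% of the HFD coixenolide and 9.95 ± 9.20% of the HFD control libraries, with 19.2% in HFD control 3, which held 224 malignant cells. Single genes with the lowest p-values were the collagen gene Col6a3 (45.1 ± 18.5 against 4.11 ± 1.505 CPM, 3.40 ± 0.58 SE), Lpl (-3.46 ± 0.80), Scg5 (-1.77 ± 0.42) and the basement membrane gene Hspg2 (0.97 ± 0.25), none of whose groups overlapped. In edgeR 0 of 18298 genes passed, 0 also when adjusted over either list alone, 283 had an unadjusted p under 0.05, and DESeq2 called 2. Groups did not overlap in 2.63% of the genes tested, where chance gives 5.71%. The preset test passed 13 lists, and 6 without HFD control 3.

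Controls on HFD and CD were compared to see what the diet alone did, and inflammatory genes were lower on HFD in the sums over all cells, macrophages, duct cells and dendritic cells. In dendritic cells, 9 of 13 pro-inflammatory macrophage genes were lower, with a median log2 difference of -1.02 (camera adjusted p = 8.41e-09, and adjusted p = 0.0399 with an estimated correlation), the 1 call kept with an estimated correlation. Of these genes, 6 passed when adjusted over the list alone and 0 over all genes. Lists were adjusted within each of 18 combinations of class and contrast, so a single such call among them can arise by chance. The mix of dendritic clusters also differed. Cluster 19 held 23 of 158, 67 of 621 and 20 of 70 dendritic cells in CD control 1 to 3. In HFD control 1 to 3 it held 48 of 149, 572 of 1001 and 334 of 1584. Il1b, a cytokine of inflammasomes, stood at 101 ± 19.05 CPM on HFD against 826 ± 566 on CD (-3.04 ± 0.52 SE, n = 3 each), Tnf at 63.3 ± 32.2 against 236 ± 119, the prostaglandin enzyme Ptgs2 at 25.97 ± 26.2 against 167 ± 103, and Il6 at 4.14 ± 0.915 against 19.8 ± 7.43. NF-kB genes were lower in 16 of 19 members, with a median of -1.19 (camera adjusted p = 2.41e-07, and adjusted p = 0.160 with an estimated correlation), and 5 passed when adjusted over the list alone. The lowest p-values in dendritic cells were those of Cbx3, a heterochromatin protein (65.3 ± 8.17 against 21.99 ± 0.580 CPM, 1.57 ± 0.26), Il1b, Timd4 (-3.25 ± 0.59), Il1r2 (-2.81 ± 0.57) and Crem (-1.30 ± 0.28), with the lowest adjusted p at 0.224. In edgeR 0 genes passed, 323 had an unadjusted p under 0.05 (389 by chance) and DESeq2 called 11, while edgeR with library type as a term called 35.

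In macrophages of the controls, 19 of 22 NF-kB genes were lower on HFD, with a median of -0.80 (camera adjusted p = 0.00026, and adjusted p = 0.783 with an estimated correlation), and 15 of 15 pro-inflammatory genes, with a median of -0.56 (camera adjusted p = 0.000455, and adjusted p = 0.783 with an estimated correlation). Il1b stood at 118 ± 27.6 against 374 ± 119 CPM (n = 3 each), and Ptgs2 at 28.6 ± 15.4 against 106 ± 34.9. The lowest p-values were those of Smim3 (-1.12 ± 0.25), the stress gene Gadd45b (81.1 ± 34.3 against 304 ± 24.04 CPM, -1.91 ± 0.44), Rgs2, a brake on G protein signalling (-1.15 ± 0.29), Lsm7 (0.81 ± 0.20) and Sertad1 (-1.13 ± 0.30). With edgeR 0 genes passed, 0 also when adjusted over either list alone, 278 had an unadjusted p under 0.05, and DESeq2 called 0. The lists that passed numbered 6, and from 3 to 10 when single libraries were left out, the lowest without CD control 3 and the highest without HFD control 1.

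Duct cells of the controls held less RNA of inflammatory genes and more of immediate early genes on HFD. Most duct cells lay in cluster 14 in the CD controls and HFD control 1, and in cluster 16 in HFD control 2 and 3. Of 22 NF-kB genes 19 were lower, with a median of -0.72 (camera adjusted p = 4.08e-08, and adjusted p = 0.536 with an estimated correlation), and Saa3 in this list turned to 1.58 without CD control 1, from -4.62. Immediate early genes, which dissociation of tissue is known to raise, were higher in 12 of 13, with a median of 0.52 (camera adjusted p = 0.000205, and adjusted p = 0.536 with an estimated correlation), led by Ier2 (989 ± 233 against 531 ± 125 CPM, n = 3 each). HFD control 1, of the second library type that is high in these genes and absent from CD, stood highest, with Junb at 2202 CPM against 701 and 1011 in HFD control 2 and 3. Cbx3 had the lowest p-value (1.02 ± 0.24), followed by Plekhs1 (-0.89 ± 0.22), Tmco6 (1.34 ± 0.34), Fam174b (0.97 ± 0.25) and C2cd4b (2.69 ± 0.68). In edgeR 0 genes passed, 0 also when adjusted over either list alone, 369 had an unadjusted p under 0.05 (667 by chance), and DESeq2 called 0. With the preset correlation 11 lists passed, 7 without CD control 2 and 6 without CD control 3.

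Stress-response genes were lower on HFD in malignant cells and in the sums over all cells. In malignant cells (n = 3 HFD and 2 CD control libraries), 21 of 23 genes of the integrated stress response were lower, with a median log2 difference of -0.73 (camera adjusted p = 3.96e-12, and adjusted p = 0.235 with an estimated correlation), and 6 passed when adjusted over the list alone against 0 over all genes. Atf4, its transcription factor, stood at 103 ± 14.1 against 326 ± 119 CPM (-1.65 ± 0.28 SE), Psat1, an enzyme of serine synthesis, at 65.3 ± 7.36 against 129 ± 23.7, the pseudokinase Trib3 at 2.92 ± 0.140 against 11.6 ± 0.321, and Atf5 at 32.2 ± 8.26 against 84.6 ± 58.3. Malignant cells of CD control 2 and 3 lay mostly in clusters 31, 2 and 32 (2487, 4388 and 2259 cells), and those of HFD control 1 and 2 mostly in clusters 18 and 26 (3092 and 1685). Cytotoxic lymphocyte genes were higher in 14 of 14 members in the same sums, with a median of 1.54 (camera adjusted p = 3.06e-05, and adjusted p = 0.8001 with an estimated correlation), Cd8a being at 4.19 ± 3.38 against 1.07 ± 0.447 CPM. T cells made up 9.95 ± 9.20% of HFD control and 1.97 ± 1.76% of CD control libraries (n = 3 each), and over all cells the list had a median of 1.501. After Atf4 the lowest p-values were those of the growth factor Fgf2 (-3.81 ± 0.66), Apobec1 (-2.04 ± 0.35), Gmds (-1.16 ± 0.21) and Foxc1 (-1.66 ± 0.30), at an adjusted p of 0.542 in edgeR. With edgeR 0 genes passed, 2 without CD control 3, 748 had an unadjusted p under 0.05 (915 by chance), and DESeq2 called 56. The preset test passed 5 lists, 10 with library type as a term, 13 without CD control 2 and 9 without HFD control 2.

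Over all cells of the controls, 22 of 23 stress-response genes were lower on HFD, with a median of -0.57 (camera adjusted p = 4.38e-09, and adjusted p = 0.200 with an estimated correlation). Atf4 was the 1 member to pass when adjusted over the list alone (96.9 ± 8.83 against 251 ± 78.5 CPM, -1.37 ± 0.24 SE, n = 3 each). Of 24 NF-kB genes 19 were lower, with a median of -0.96 (camera adjusted p = 2.63e-12, and adjusted p = 0.0942 with an estimated correlation), among them Tnfaip3 (25.2 ± 8.68 against 99.95 ± 44.9 CPM) and the neutrophil chemokine Cxcl2 (272 ± 158 against 1552 ± 921). The make-up of the sums differed too, as CD control 1 held 0 malignant cells and 39.6% plasma cells, haemoglobin genes were lower on HFD in 4 of 4 (median -4.39, camera adjusted p = 0.00198, and adjusted p = 0.566 with an estimated correlation) and cytotoxic lymphocyte genes higher in 13 of 14 (camera adjusted p = 0.00173, and adjusted p = 0.891 with an estimated correlation). Sertad1 (-1.23 ± 0.26), Gadd45b (-2.02 ± 0.44), Gmds (-0.92 ± 0.20) and the cyclin gene Ccnl1 (-1.03 ± 0.23) followed Atf4 by p-value. In edgeR 0 genes passed, 340 had an unadjusted p under 0.05, where chance gives 986, and DESeq2 called 7. The preset test passed 8 lists, and 13 with library type as a term.

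The difference between the coixenolide effects on the 2 diets was tested as an interaction. In macrophages, all 31 proliferation genes (median 1.34, camera adjusted p = 2.58e-13, and adjusted p = 0.457 with an estimated correlation) and all 30 interferon genes (median 1.27, camera adjusted p = 4.32e-09, and adjusted p = 0.519 with an estimated correlation) had higher effects on HFD than on CD. In duct cells the same held for 22 of 22 cholesterol synthesis genes (median 1.62, camera adjusted p = 1.13e-12, and adjusted p = 0.376 with an estimated correlation), with Nsdhl at 2.09 ± 0.59, and for 21 of 22 NF-kB genes (median 2.13, camera adjusted p = 8.18e-11, and adjusted p = 0.376 with an estimated correlation). Over all cells, effects were higher on HFD for 31 of 31 proliferation genes (median 1.77, camera adjusted p = 6.95e-20, and adjusted p = 0.220 with an estimated correlation) and lower for 24 of 24 fatty acid oxidation genes (median -0.59, camera adjusted p = 1.16e-07, and adjusted p = 0.220 with an estimated correlation), with Ppara at -3.19 ± 0.89. In dendritic cells they were higher for 28 of 29 interferon genes (median 1.09, camera adjusted p = 5.87e-10, and adjusted p = 0.579 with an estimated correlation) and 25 of 31 proliferation genes (median 0.30, camera adjusted p = 0.00034, and adjusted p = 0.705 with an estimated correlation). No member of these lists passed, also when adjusted over the list alone. The sums over all cells moved with tissue make-up too, since CD control 1 and CD coixenolide 1 and 2 held 0 malignant cells. Cluster mix differed within classes as well. Cluster 8 held 505 of 516 and 433 of 448 macrophages in CD coixenolide 1 and 2, and 247 of 312 in CD control 1. Cluster 16 held 2264 and 2400 duct cells in CD coixenolide 1 and 2, against 83, 185 and 2 in CD control 1 to 3. The macrophage and duct differences are thus not shown to be changes within a single kind of cell.

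Of single genes, edgeR called 0 for this interaction in the sums over all cells, macrophages, duct cells and dendritic cells, with 900, 904, 900 and 122 genes at an unadjusted p under 0.05, and DESeq2 called 21, 12, 1 and 2. Without CD coixenolide 3, edgeR called 292 genes over all cells, 524 in macrophages and 42 in duct cells. Likewise 0 genes were called under coixenolide in both diets. Across genes, which are not independent replicates, the log2 differences on the 2 diets correlated at r = -0.15 over all cells, -0.42 in macrophages, -0.42 in duct cells and -0.07 in dendritic cells.

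Whether genes altered by HFD moved back under coixenolide was asked from the covariance of the 2 sets of log2 differences across genes. It lies below 0 with no effect at all, because both use the HFD controls. It was -0.162 over all cells, against a mean of -0.495 in 20 simulations with no effect, -0.117 against -0.183 in macrophages, -0.0901 against -0.183 in duct cells, -0.0786 against -0.112 in dendritic cells and -0.275 against -0.345 in malignant cells. In each class the observed value lay above the simulated range, and the HFD controls were too few to divide between the comparisons. The simulations gave all libraries the same mean of a gene and left out the library types described below. The second type is absent from CD and unevenly shared by the HFD groups, so it enters both sets of differences. A value above the simulated range therefore cannot decide for or against reversal.

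The HFD libraries fell into 2 types by their expression, and the cause was not settled. HFD control 1 and HFD coixenolide 3 and 4 held 44.3, 43.6 and 64.7 CPM of Gm11175, a predicted gene, against 0.478 to 3.53 in the other 10 libraries, and the barcodes of HFD control 1 and HFD coixenolide 3 were 27 bases long against 24 wherever else they are listed. All libraries were placed by their level of Gm11175. No barcode length is given for HFD coixenolide 1 and 4, HFD control 2 and CD coixenolide 2, so these are placed by Gm11175 alone. Library type as a term called 381 genes over all cells, 487 in macrophages, 1181 in duct cells, 178 in dendritic cells and 2219 in malignant cells (edgeR). In macrophages the second type was higher in Junb (log2 difference 2.76) and Nr4a1 (2.66), both immediate early genes, in Junos (3.15), antisense to Jun, and in Myc (1.92). Since the counting is not stated to use strand, reads of Junos and Jun cannot be told apart. The type joins libraries of both HFD groups and none of CD, so it parts each HFD group but is tied to diet.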

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

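The tests of free RNA, of removal by coixenolide and of library type were chosen after the results they concern had been seen.

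HFD coixenolide 1 held more T cells, dendritic cells, endocrine cells and acinar cells than the other 3 libraries of its group. T cells made up 12.6% of its cells (exact binomial 95% interval 11.9 to 13.4%) against 0.633 to 2.47%, and dendritic cells 24.8% (23.8 to 25.7%) against 0.623 to 2.19%. Endocrine cells made up 2.14% (1.84 to 2.48%) against 0.0155 to 0.159%, and acinar cells 1.15% (0.930 to 1.41%) against 0 to 0.159%. The gap to the nearest library, as a part of the whole range, was 0.847 for T cells, 0.935 for dendritic cells, 0.932 for endocrine cells and 0.862 for acinar cells. Cyp2e1 in the all-cell sums reached 0.411 CPM in HFD coixenolide 4, with a gap of 0.847 of the range. Of 34 shares and gene levels of these 4 libraries examined in this way 5 stood out. Chance gives about 1 in 20 where values are independent, which these are not. Groups of 3 libraries were too small to be examined. Malignant cells made up 7.06% of HFD coixenolide 1 against 55.0 to 74.9% of the other 3. Macrophages (13.9% against 16.4 to 17.2%) and fibroblasts (0.281% against 1.14 to 5.50%) were lower there, so few malignant cells alone do not account for the shares that stood out.

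The coixenolide effect differed between the diets in several gene lists, by the interaction test with the preset correlation. These were 16 lists in duct cells, among them cholesterol synthesis and NF-kB genes, 11 over all cells, 10 in macrophages, among them interferon and proliferation genes, and 4 in dendritic cells. With an estimated correlation 0 of these lists passed. The mix of clusters within macrophages and duct cells also differed between the libraries, as given above. Without the 3 libraries that hold no malignant cells 3 lists passed in duct cells and 5 in macrophages, and in dendritic cells 0 passed without CD coixenolide 2, 2 without HFD control 3, and 8 without HFD control 1 or HFD coixenolide 1.

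CD control 1 and CD coixenolide 1 and 2 held no malignant-like cells. Removal of malignant cells by coixenolide does not account for all of them, because 1 of the 3 is a control library. Malignant cells broken during processing would leave free RNA, and 6 genes restricted to malignant cells summed to 6.47, 10.7 and 1.75 CPM in their macrophages, against 8.75 in HFD control 3 and 10.1 in HFD coixenolide 1, which hold few malignant cells, and 42.3 to 247 CPM in the others. The median of the 6 genes was 0 CPM in the 3 libraries and at least 1.03 in the others, and a single gene, 3830403N18Rik, held 94.1, 98.1 and 87.5% of those UMIs. The sum in CD coixenolide 1 passed that of HFD control 3 while the median did not, so sum and median point different ways. The sum rests on 3830403N18Rik, however. Each of the other genes had 0 or 1 UMI in macrophages of the 3 libraries, in 2625608 to 5025263 UMIs. These genes had 8 to 67 each in HFD control 3 (of 22394478) and 0 to 25 in HFD coixenolide 1 (of 7255671). For these genes the values argue against free RNA in the 3 libraries. Loss that left no free RNA and tissue sampled outside the tumour cannot be told apart.

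HFD control 1 and HFD coixenolide 3 and 4 stood apart in each class tested. Of the 148 genes that parted them in macrophages and lay at a lower level in malignant cells, 96.6% differed in the same direction in malignant cells, with r = 0.930 across these genes, which are not independent replicates. Free RNA from malignant cells could not raise or lower these genes so in malignant cells themselves, nor add much of genes held at a lower level there, so it does not account for the shift. The 148 genes were chosen to lie higher in macrophages, however. Macrophage RNA counted in malignant cells would move them the same way, and this was not tested. Handling of the tissue, library preparation or counting is consistent with a shift shared by all classes such as that of Junb and Ier2. An earlier test asked whether predicted genes are more frequent among the genes higher in these libraries than among those tested. They were over all cells (38.3% against 22.7%, Fisher p = 4.13e-08), in malignant cells (28.9% against 23.4%, p = 1.52e-06) and in duct cells (11.6% against 8.65%, p = 0.0125), and not past 0.05 in macrophages (10.7% against 8.20%, p = 0.123) or dendritic cells (6.62% against 3.50%, p = 0.0563). Genes are not independent in this test, and a state of the whole tumour stays open.

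Lipid-associated macrophage genes were lower under coixenolide in HFD, in 7 genes chosen after their values were seen. Gpnmb, Lpl, Cd36, Mmp12, Ctsk, Lipa and Spp1 had a mean log2 difference of -2.86, from -3.34 to -2.38 without single libraries, for which no p is given because the choice of genes fixes it. In CD it was 3.12 (exact permutation p = 0.200). The difference was not lost within the library types, with medians of -3.07 within the first (2 against 2 libraries) and -2.81 within the second (2 against 1). For all of these genes but Spp1, every HFD coixenolide library lay below every HFD control. Their choice thus fixed a lower level within each type, and the test cannot exclude library type. Within cluster 12 the median was -0.99 against -3.13 over all macrophages, consistent with a different mix of macrophage clusters as a large part of the difference. Medians of -1.23, -1.31 and -0.56 were left within clusters 6, 8 and 9, and 4 of the 7 genes also lead a macrophage cluster, so the test is not independent of the genes.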

How the results depend on the processing

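Library type as a term, removal of the 3 libraries with no malignant cells and removal of high doublet scores were chosen after the data were seen. Of the gene and share results under the alternatives, 3115 kept direction and side of the threshold, 75 newly passed and 27 changed direction. No gene or share passed in the main analysis, so a call could be gained but not lost. Keeping the side of the threshold thus means only that a result still did not pass, and the 3115 inform on direction alone. Of the counts, 593 stayed within 1.5 times and 77 moved. These include counts of genes and shares called, which also started from none. Where a library left out leaves a single one in a group, that library is assumed to vary like the other groups. The causes of these shifts were not tested.

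DESeq2 called more genes than edgeR. For coixenolide in CD it called 83 genes over all cells, 4 in macrophages, 25 in duct cells and 1 in dendritic cells, and in HFD 1 in dendritic and 2 in malignant cells. For HFD against CD it called 7 over all cells, 11 in dendritic and 56 in malignant cells, and for the interaction 21 over all cells, 12 in macrophages, 1 in duct and 2 in dendritic cells. With no filter on low counts edgeR called 17 genes for HFD against CD and 1 for coixenolide in malignant cells, and 2 for coixenolide in CD in duct cells. With an estimated correlation 0 lists passed in 17 of 18 combinations and 1 in dendritic cells of the controls. With library type as a term, 35 genes passed in dendritic cells of the controls, and lists went from 8 to 13 over all cells and from 5 to 10 in malignant cells of the controls, and from 14 to 7 for coixenolide in HFD over all cells.

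The replicate numbers do not pair the libraries, as correlations of the same number ran from -0.67 to 0.41. With a block on the number, Etv4 over all cells for coixenolide in HFD went from 0.68 to -0.19, and lists went from 14 to 7.

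Without the 3 libraries that hold no malignant cells, Saa3 for HFD against CD was 0.86 in dendritic cells and 1.57 in duct cells, and for coixenolide in CD 0.41 in duct cells. Bub1 (0.00656), Bub1b (0.0192) and Diaph3 (0.00209) in macrophages for coixenolide in CD lay near 0. For shares, HFD against CD gave 0.51 for duct and -0.97 for malignant cells, and coixenolide -2.01 for duct and 0.47 for malignant cells. Lists went from 15 to 2 in duct cells and 14 to 7 in macrophages for coixenolide in CD, from 1 to 3 in dendritic cells for coixenolide in HFD, and from 16 to 3 in duct cells and 10 to 5 in macrophages for the interaction. As a share of non-malignant cells, macrophages for HFD against CD were at 0.23.

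Leaving out single libraries, genes called for coixenolide in CD ranged from 0 to 825 over all cells, 0 to 583 in macrophages, 0 to 240 in duct and 0 to 1 in dendritic cells, and for the interaction from 0 to 292 over all cells, 0 to 524 in macrophages and 0 to 42 in duct cells, each highest without CD coixenolide 3. In malignant cells of the controls 0 to 2 genes were called, the most without CD control 3. Fitted Tpsb2 in dendritic cells ran from 0 (without CD coixenolide 3) to 11.13, which is no fold since its controls are at 0. Saa3 in duct cells for HFD against CD ran from -5.19 to 1.58 (without CD control 1). For coixenolide in HFD, Ikzf2 over all cells ran from -2.52 to 0.0743 and Ccl5 in malignant cells from -2.001 to 0.34, both highest without HFD control 3.

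Shares without single libraries ran, for coixenolide, from -0.27 to 1.70 in duct cells (below 0 without CD coixenolide 1 or 2 or HFD coixenolide 1 or 3), -0.33 to 0.69 in macrophages (below 0 without CD control 1, CD coixenolide 3 or HFD control 1) and -3.68 to 0.17 in malignant cells (above 0 without CD control 3). For HFD against CD macrophages ran from -0.68 to 0.35 (above 0 without CD control 2, CD coixenolide 3 or HFD control 1).

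Lists without single libraries numbered, for coixenolide in HFD, 3 to 17 over all cells (3 without HFD control 3, 7 without HFD coixenolide 3, 8 without HFD control 2), 3 to 12 in macrophages (3 without HFD control 3, 11 without HFD control 1, 12 without HFD coixenolide 1), 1 to 9 in dendritic cells (9 without HFD control 1, 7 without HFD control 2, 5 and 6 without HFD coixenolide 1 and 2) and 6 to 15 in malignant cells (6 without HFD control 3, 8 without HFD coixenolide 3). For coixenolide in CD they numbered 8 to 14 in macrophages (8 without CD coixenolide 1) and 2 to 5 in dendritic cells (5 without CD control 1 or CD coixenolide 3). For HFD against CD they numbered 3 to 10 in macrophages (3 without CD control 3, 10 without HFD control 1), 6 to 12 in duct cells (6 without CD control 3, 7 without CD control 2) and 6 to 13 in malignant cells (13 without CD control 2, 9 without HFD control 2). For the interaction in dendritic cells they numbered 0 to 8 (0 without CD coixenolide 2, 2 without HFD control 3, 8 without HFD control 1 or HFD coixenolide 1).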

Other observations

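Malignant cells of the HFD coixenolide libraries also held more RNA of fatty acid synthesis genes. Of 13 fatty acid synthesis genes 12 were higher, with a median log2 difference of 0.38 (camera adjusted p = 0.000331, and adjusted p = 0.454 with an estimated correlation), with Acly, which makes cytosolic acetyl-CoA, at 71.7 ± 14.4 CPM (SD, n = 4) against 50.7 ± 12.1 (n = 3). The malignant cells of HFD control 1 and 2 lay mostly in other clusters than those of HFD coixenolide 2 to 4, so this is not shown to be a change within one kind of malignant cell. In the extracellular matrix list Col6a3 passed when adjusted over the list alone, and 0 members over all genes. Lpl in the lipid uptake list did so too, with Cd36 at 1.60 ± 0.765 against 11.9 ± 14.5 CPM. Lpl and Cd36 are macrophage genes here, whose level in malignant sums moves with that in macrophages.

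Duct cells of CD coixenolide libraries held less RNA of 30 of 30 interferon genes (median -0.77, camera adjusted p = 6.60e-09, and adjusted p = 0.414 with an estimated correlation), with Irf1, an interferon-induced factor, at 83.2 ± 28.1 against 143 ± 33.4 CPM (n = 3 each). All 22 cholesterol synthesis genes were lower too (median -1.01, camera adjusted p = 6.60e-09, and adjusted p = 0.414 with an estimated correlation), with the sterol sensor partner Insig1 at 6.61 ± 0.812 against 16.05 ± 3.03 CPM. In dendritic cells of the controls, Isg15 passed on HFD when adjusted over the interferon list alone (158 ± 9.39 against 467 ± 139 CPM), with 25 of 29 members lower (camera adjusted p = 9.07e-06, and adjusted p = 0.735 with an estimated correlation). Haemoglobin genes were lower in duct cells of HFD than of CD controls, and 4 of 4 passed over that list alone (camera adjusted p = 0.00354, and adjusted p = 0.536 with an estimated correlation). CD control 1 carried this, with Hbb-bs at 500 CPM against 5.85 and 7.95 in CD control 2 and 3 and 0.635 to 5.73 in the HFD controls, and with 388 erythroid cells against at most 8 in those libraries.

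The counts of splits were planned, and the comparison of splits with library types was chosen after the data were seen. Other divisions of the libraries into groups of the same sizes were fitted to see how often they give as much as the real one. The real one gave 0 genes throughout, which every split reaches, so the gene counts cannot decide this and only the lists can. For coixenolide in CD there are 10 splits, too few for a share under 0.05. Over all cells the real one gave 0 genes and 14 lists, as did 10 and 3 splits or more, and the highest other 1649 and 14. In macrophages it gave 0 and 14 (10 and 2 splits, highest other 2169 and 17), and in duct cells 0 and 15 (10 and 3 splits, highest other 1 and 17). The split that sets CD control 1 and CD coixenolide 1 and 2 against the rest gave the 1649 and 2169 genes, which points to a structure of the libraries other than coixenolide.

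For coixenolide in HFD chance cannot be excluded in 35 splits over all cells, macrophages, dendritic and malignant cells. The real split gave 0 genes in each, which any split reaches (35 of 35 splits), against a highest other of 884, 633, 262 and 2738. It gave 14, 6, 1 and 13 lists (2, 28, 35 and 5 splits with as many), against a highest other of 15, 13, 10 and 15. For the 14 lists over all cells 2 of 35 is a share over 0.05. In duct cells, with 10 splits, too few for a share under 0.05, it gave 0 genes and 9 lists (10 and 4 splits), with a highest other of 2136 and 13. The splits with the most genes are those by library type, which points to a structure of the libraries, and with library type as a term the lists over all cells numbered 7.

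For HFD against CD in the controls there are 10 splits, too few for a share under 0.05. The real one gave 0 genes over all cells, in macrophages, duct and dendritic cells (10 splits each, highest other 0), and 8, 6, 11 and 6 lists (7, 8, 4 and 8 splits), with a highest other of 15, 14, 17 and 10. For the interaction chance cannot be excluded in 30 splits drawn over all cells, macrophages and duct cells. The real one gave 0 genes in each (30 of 30 splits, highest other 0, 3 and 7) and 11, 10 and 16 lists (13, 16 and 4 splits), with a highest other of 15, 15 and 18.

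Pairs of libraries were compared within each group, and none were copies, since the closest of these pairs, CD coixenolide 1 and 2, differed far beyond sampling noise (chi-square over degrees of freedom 41.3 in 14838 genes).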
